A study of Homo sapiens with 12 samples.

How the data were processed

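RNA from 12 cultures of IOMM-Lee, a human cell line from an anaplastic meningioma, was measured on Affymetrix whole-transcript arrays. Per the labels' protocols, 6 cultures received a negative control siRNA (siCtrl) and 6 received 1 siRNA against ELAVL1, the gene that encodes the RNA-binding protein HuR (siHuR). The siRNA dose was 17 nM, RNA was taken 72 hours after transfection, and the samples were labelled with biotin. The extraction protocol gives total RNA while the molecule label gives polyA RNA, which leaves open how fully RNAs without a poly(A) tail, such as small Cajal body RNAs, were represented. The series describes the 6 samples of each group as biological replicates.

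The submitters' processing notes name oligo and RMA, without versions. The deposited table held 44629 probe sets for 12 arrays as linear intensity values. RMA output is usually on a log2 scale and normalized between arrays, but the deposited intensity values lay between 24.5 and 15059.5 and their medians differed between arrays, from 60.0 to 76.1. How the probes of a probe set were summarised is not given in the sources used here. The analysis had been planned for log2 values, so the scale used here was fixed after the unit was seen. The background was corrected with limma's normexp method with an offset of 50, log2 was taken, and the arrays were quantile normalized over all probe sets. The offset compresses the fold changes of dim genes. No detection calls were used here, and the number of arrays limits the precision.

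Probe sets were named through the platform annotation. It gave 15835 probe sets 1 gene symbol, 0 several symbols, and left 28794 unnamed here. All 15835 entrez identifiers were found in a RefSeq gene table of assembly GRCh38.p14, and 0 symbols changed. The build of the array design is not given in the sources used here, so no coordinates are given. Of the 14812 genes, 651 had more than 1 probe set, and the probe set with the highest mean over the 12 arrays stood for the gene. ELAVL1 was not among the genes named here, so its knockdown was not analysed here.

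Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, as siHuR minus siCtrl, with Benjamini-Hochberg adjustment over 14812 genes and a threshold of 0.05. A second count required a change of at least 1.5-fold. Errors of the log2 changes of genes and probe sets are standard errors of that fit with 6 arrays a group. The fit treats the arrays of a group as independent. As given below, siCtrl arrays 1 to 3 differed from siCtrl arrays 4 to 6, so these errors and the p-values may be too small. Errors of the immediate-early list mean are instead standard errors of the difference between the group means of that list over arrays. Within replicate numbers they use only the arrays of those numbers. Gene lists were written from general knowledge before the data were examined, 29 in all, and 28 had the minimum of 5 tested members. Written members that were not among the genes named here were not tested. The tests covered 27 of 46 written p53 targets, 32 of 55 hypoxia-responsive genes and 15 of 76 oxidative phosphorylation genes. Each list result holds for its tested members only. The list of reported HuR target mRNAs came from work in other systems. Lists were tested with camera at a preset correlation between genes of 0.01 and again with an estimated correlation, with adjustment over 28 lists.

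The genes named were chosen by a rule written before the data were examined. It took ELAVL1 first, then the 12 largest rises and the 12 largest falls past the threshold. Those genes needed all 6 siHuR arrays on one side of all siCtrl arrays and a mean in the higher group at or above the median of all named genes. Noncoding and clone symbols were left out. From each list the rule took the 4 members with the smallest adjusted p, and 6 for the hypoxia, mitosis and DNA replication lists. Genes outside the rule are marked in the text as chosen after their values were seen.

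The steps were tested on simulated data for siHuR against siCtrl, drawn for the same 14812 genes from the real means, spreads and array medians. In 10 simulations with 200 changed genes each, 79.0% of the 1.2-fold changes and 99.4% of the 1.5-fold changes were recovered. The changed genes were drawn only from genes with a mean at or above the median of all genes. Recovery among dimmer genes was not tested. The median recovered change was 1.18-fold for 1.2-fold changes and 1.87-fold for 2-fold changes. Of 1979 calls, 4.80% were false. camera called all 20 simulated lists of 30 genes shifted by 0.15 and 1 of 80 unshifted lists, with genes drawn independently.

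The alternatives tried were other background corrections and normalizations, a filter on dim genes, other rules for a gene's probe sets, a block of the replicate number, other prior and weight settings, a rank-sum test, other list tests and leaving out each array. Those on the background correction, the deposited scale, the grouping of replicate numbers, the first probe set and the permutation of list means were chosen after seeing the data.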

Results

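The data comprised 12 arrays of IOMM-Lee cells, 6 with control siRNA and 6 with ELAVL1 siRNA. The series title places HuR in meningioma cell growth and resistance to hypoxia, and the comparison asks how mRNA levels differ once HuR is targeted. Replicates correlated with r from 0.991 to 0.994 in siCtrl and from 0.994 to 0.996 in siHuR, across all probe sets on log2 of the values as deposited. The first principal component (39.4% of variance) separated the groups. The second (10.0%) separated siCtrl arrays 1 to 3 (3.84 to 5.00) from siCtrl arrays 4 to 6 (-5.60 to -3.31), while siHuR arrays lay between -0.511 and 0.261. The median deposited intensity was 69.2 ± 6.58 (SD, n = 6) in siCtrl and 63.9 ± 2.87 (SD, n = 6) in siHuR (two-sided exact permutation test, p = 0.108; the smallest p possible is 0.00216).

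CCL2, a chemokine that attracts monocytes, rose by 2.28 ± 0.05 on the log2 scale, or 4.86-fold (adjusted p = 1.08e-16). The complement component C3 rose by 1.31 ± 0.07 (2.47-fold). ESM1, a secreted endothelial proteoglycan, fell by 1.22 ± 0.04 on the log2 scale (2.34-fold lower; adjusted p = 1.74e-13), and PLXNA4, a semaphorin receptor, fell by 1.02 ± 0.04. Across 14812 genes, 2223 changed, 1170 higher and 1053 lower in siHuR. Most changes were small, with a median size of 1.12-fold, and 47 genes changed at least 1.5-fold, 23 higher and 24 lower. In 609 genes all siHuR arrays lay above all siCtrl arrays and in 629 below, together 8.36% of genes where chance gives 0.217%. The split of calls depended on the scaling. Without normalization between arrays the median of all genes moved by -0.0733 and 9.60% of 1146 calls were higher, with log2 of the values as deposited it moved by -0.104 and 8.25% of 1442 calls were higher, and with arrays only re-centred 35.0% of 1493 calls were higher, against 52.6% in the main setting.

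**Figure D1:**
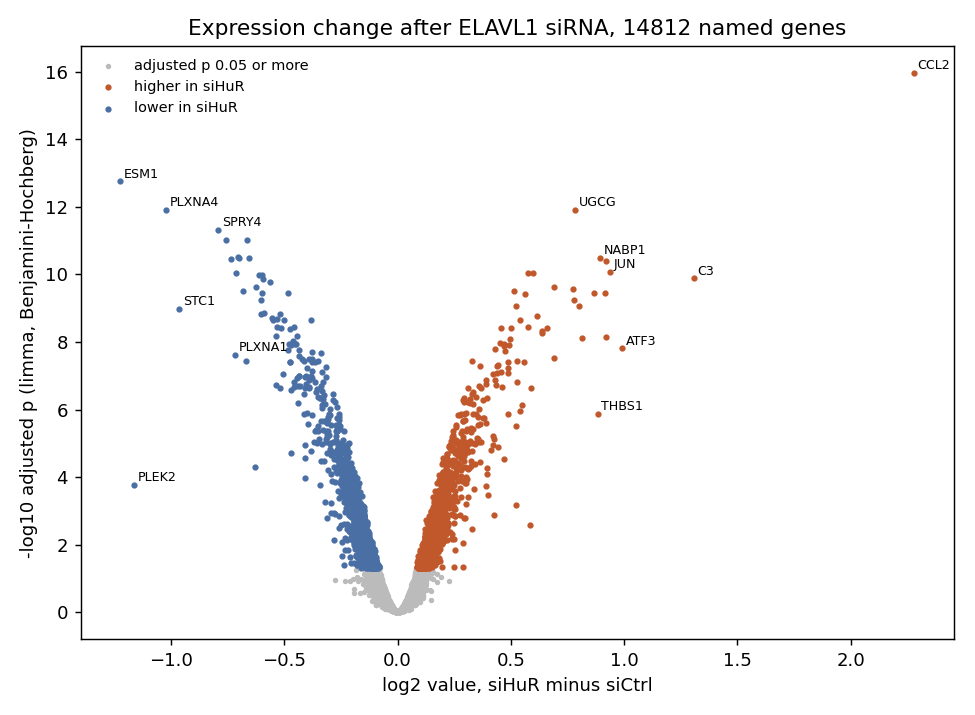
Change of each of 14812 named genes, as log2 siHuR minus siCtrl (x axis) against -log10 of the limma adjusted p (y axis), with genes past 0.05 in colour. CCL2 stands apart at 2.28, and ESM1 at -1.22 is the lowest labelled gene.

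Other genes with large rises were transcription factors of the stress response, ATF3 (0.99 ± 0.08) and JUN (0.94 ± 0.05), and the cytokine receptor IL7R (0.92 ± 0.07). ATF3 rose by 0.72 within replicate numbers 1 to 3 and by 1.27 within numbers 4 to 6. The DNA-binding protein gene NABP1 rose by 0.89 ± 0.05, the vasoconstrictor gene EDN1 by 0.81 ± 0.06 (0.60 within numbers 1 to 3 and 1.03 within numbers 4 to 6), the protease inhibitor SLPI by 0.80 ± 0.05 and the glucosylceramide synthase UGCG by 0.78 ± 0.03. C4B (0.92 ± 0.06) and C4A (0.87 ± 0.05) rose together, but these near-identical genes share probe sequence and their separate values are uncertain. THBS1, a secreted matrix glycoprotein, rose by 0.88 ± 0.10, by 0.60 within replicate numbers 1 to 3 and by 1.16 within numbers 4 to 6.

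Large falls were measured for the secreted glycoprotein STC1 (-0.96 ± 0.06), the signalling inhibitor SPRY4 (-0.79 ± 0.04), TMEM158 (-0.76 ± 0.04) and the Wnt antagonist SFRP1 (-0.71 ± 0.04). The semaphorin co-receptor NRP1 (-0.74 ± 0.04) and PLXNA1 (-0.72 ± 0.06) fell as well. KIAA1549L (-0.71 ± 0.04), the neurotensin receptor NTSR1 (-0.70 ± 0.04) and NPTX1 (-0.68 ± 0.04) also fell. PLEK2 fell by 1.16 ± 0.19 on the log2 scale, with a siCtrl SD of 0.645. Its change was -0.58 within numbers 1 to 3 and -1.76 within numbers 4 to 6.

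**Figure D2:**
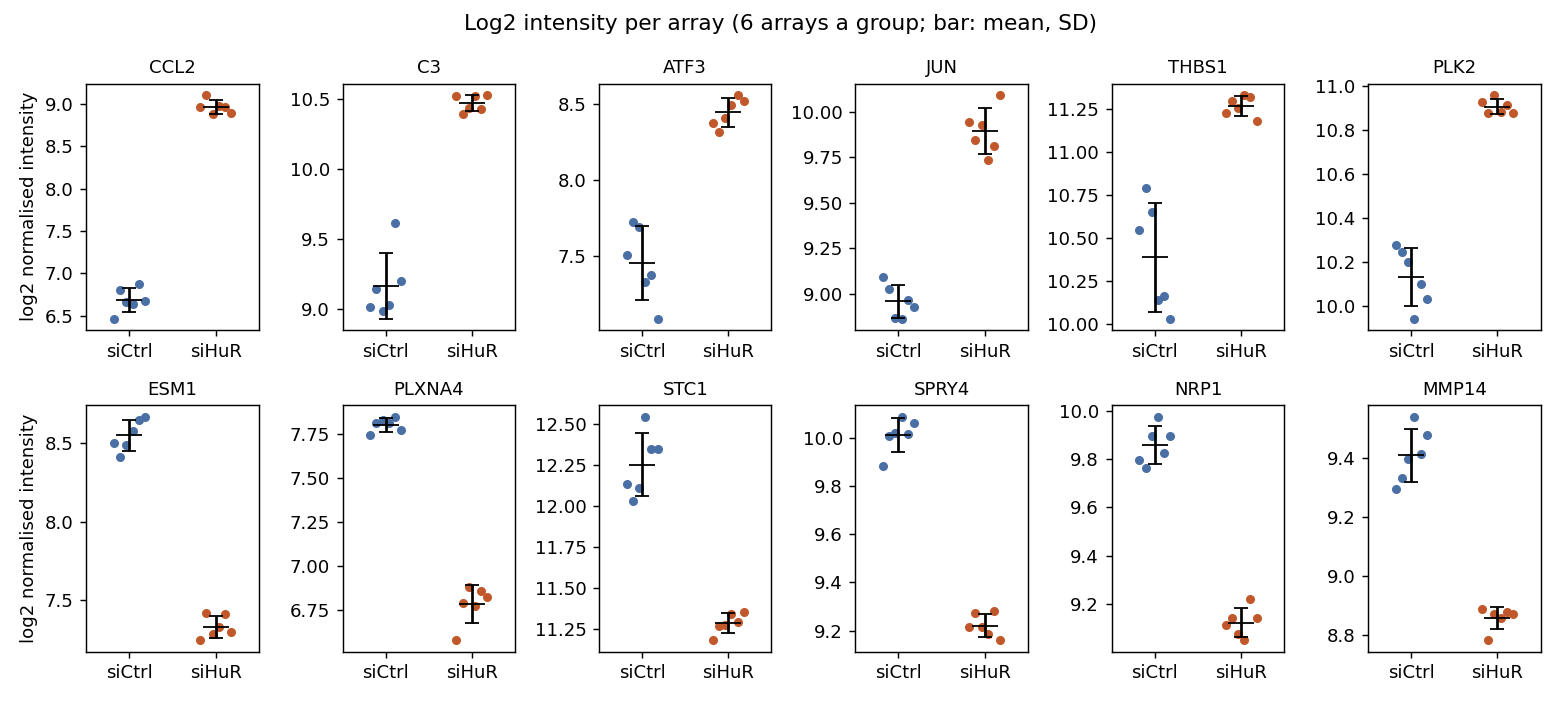
Log2 normalised intensity (y axis) of 12 named genes on each of 6 siCtrl and 6 siHuR arrays, with mean and SD as bars. In each of the 12 panels the groups do not overlap, and CCL2 moved from a mean of 6.68 to 8.96.

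The list written for immediate-early genes, which respond within minutes to growth factors and stress, was higher. Of 27 tested, 19 rose, 5 fell and 3 did not pass, and 19 rose and 6 fell adjusted over the list alone (camera adjusted p = 1.85e-07; adjusted p = 0.0377 with an estimated correlation). JUN rose by 0.94 and IER2 by 0.56 ± 0.04. The 5 that fell were SPRY4, the phosphatase DUSP4 (-0.60 ± 0.04) and, chosen after their values were seen, ETV4 (-0.53), KLF2 (-0.38) and ETV5 (-0.20). Of these, SPRY4, DUSP4, ETV4 and ETV5 were also members of a list of ERK output genes described below. The 5 falls are therefore not read as falls of immediate-early genes in the strict sense. The mean rise of the list was 0.21, with 0.112 without normalization between arrays and 0.114 as deposited, and with 0.15 ± 0.03 within replicate numbers 1 to 3 and 0.27 ± 0.02 within numbers 4 to 6.

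Targets of p53 were also higher, with 15 of 27 risen, 1 fallen and 11 not passing, and with 16 risen and 1 fallen adjusted over the list alone (camera adjusted p = 2.49e-08; adjusted p = 0.0377 with an estimated correlation). CDKN1A and MDM2 were not among the tested members. The kinase PLK2 rose by 0.78 ± 0.05, TP53INP1 by 0.42 ± 0.05, TRIM22 by 0.38 ± 0.04 and RPS27L by 0.28 ± 0.03. The gene that fell, CPT1C (-0.21), was chosen after its values were seen. The mean change of the list was 0.16, with 0.0578 without normalization between arrays and 0.0561 as deposited, and the list was called higher in both.

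Splicing factors were called higher relative to other genes, with a list mean of 0.06, and that mean was -0.0312 without normalization between arrays and -0.0365 as deposited. Of 53 tested, 14 rose, 1 fell and 38 did not pass, and 20 rose and 2 fell adjusted over the list alone (camera adjusted p = 2.38e-05; adjusted p = 0.0432 with an estimated correlation). PTBP2 rose by 0.27 ± 0.03, SRSF7 by 0.26 ± 0.04, TIAL1 by 0.24 ± 0.03 and SNRNP70 by 0.17 ± 0.03. The rise of TIAL1 rested on 1 of 2 probe sets, and the other gave -0.00401 (adjusted p = 0.984 over all probe sets). PRPF8 (-0.11), chosen after its values were seen, fell.

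Of 36 reported HuR target mRNAs, 11 rose, 1 fell and 24 did not pass, and 12 rose and 2 fell adjusted over the list alone. camera called the list higher (adjusted p = 0.000656; adjusted p = 0.123 with an estimated correlation). The members with the smallest p were JUN, ATF3, DUSP1 (0.47 ± 0.04) and the small GTPase RHOB (0.62 ± 0.04). NUMB (-0.16), chosen after its values were seen, fell. The mean of the HuR target list was 0.151, with 0.0567 without normalization between arrays and 0.0453 as deposited, and with 0.106 within numbers 1 to 3 and 0.195 within numbers 4 to 6. A further list was written for proteins that bind AU-rich elements, the sequence class HuR recognises. It also held binders of other sequences, such as the poly(C) binding proteins PCBP1 and PCBP2. camera called this mixed list higher (adjusted p = 0.00484, and adjusted p = 0.123 with an estimated correlation). Its mean was 0.06, but -0.0300 without normalization between arrays and -0.0354 as deposited. Of 17, 4 rose, 1 fell and 12 did not pass (6 and 1 adjusted over the list alone). NCL rose by 0.17 ± 0.03 and IGF2BP3 fell by 0.18 ± 0.04 on the log2 scale. The call of this list was lost with arrays re-centred (adjusted p = 0.0672) and without normalization between arrays (adjusted p = 0.0611). PUM2 (0.11 ± 0.03) rose, but was -0.00151 as deposited.

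**Figure D3:**
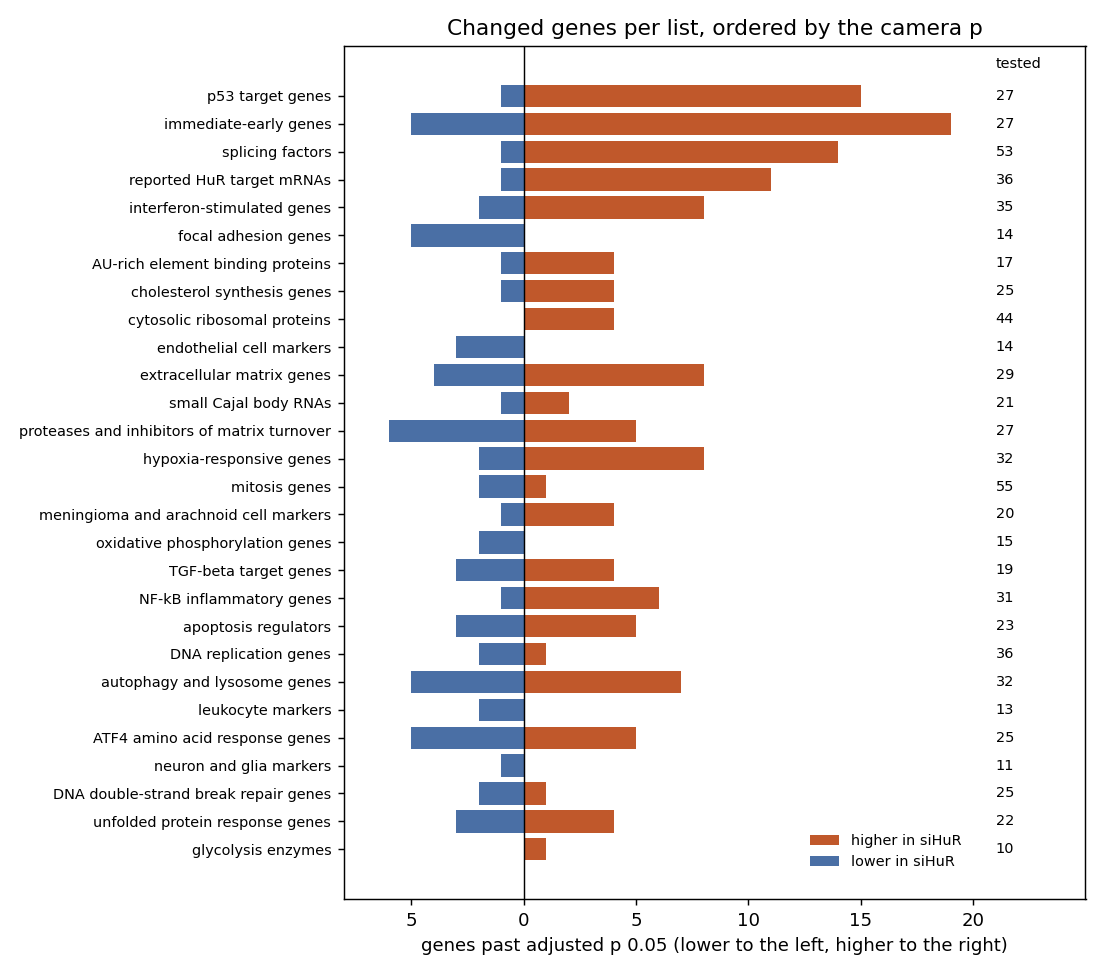
Number of members past adjusted p 0.05 in each of 28 gene lists, lower in siHuR to the left and higher to the right, with the number tested beside each bar. Immediate-early genes had 19 higher and 5 lower; the mean of splicing factors, with 14 higher and 1 lower, was -0.0312 without normalization between arrays.

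Interferon-stimulated genes were called higher (mean 0.09; -0.00778 without normalization between arrays and -0.0161 as deposited), with 8 of 35 risen, 2 fallen and 25 not passing, and 12 and 2 adjusted over the list alone (adjusted p = 0.00153; adjusted p = 0.463 with an estimated correlation). The antiviral gene IFIT2 rose by 0.48 ± 0.04, BST2 by 0.26 ± 0.04 and HERC6 by 0.26 ± 0.05, and the 2 that fell, IFITM2 (-0.20) and ISG20 (-0.14), were chosen after their values were seen. Within numbers 4 to 6 the interferon list was not called (adjusted p = 0.316). Cholesterol synthesis genes had 4 of 25 higher and 1 lower, with 20 not passing and the same counts adjusted over the list alone, and a mean of 0.05 that was -0.0463 without normalization between arrays and -0.0571 as deposited (adjusted p = 0.0285; adjusted p = 0.384 with an estimated correlation). The call of the cholesterol list was lost without siCtrl 5 (adjusted p = 0.0719), with arrays re-centred (0.176), without normalization between arrays (0.170), as deposited (0.0717), among the brighter genes (0.153) and within numbers 1 to 3 (0.0549). INSIG1 rose by 0.27 ± 0.03 and the desaturase SCD by 0.28 ± 0.04, while ACLY fell by 0.16 ± 0.04 on the log2 scale. Cytosolic ribosomal protein genes had 4 of 44 higher, 0 lower and 40 not passing, and the same adjusted over the list alone (adjusted p = 0.0489; adjusted p = 0.476 with an estimated correlation). Their mean was 0.03, but -0.0586 without normalization between arrays and -0.0648 as deposited, and the call was lost in 17 alternatives. These included arrays re-centred (adjusted p = 0.264), both sets of replicate numbers (0.135 and 0.0635) and leaving out any 1 of siCtrl 1, 2, 4 and 6 and siHuR 2 and 5 (from 0.0572 to 0.113). RPL32 rose by 0.28 ± 0.05 and RPS19 by 0.13 ± 0.03.

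Focal adhesion genes were the called list that was lower. The list had been written with integrins, but its 14 tested members were focal adhesion linkers, adaptors and kinases, and integrin genes were not analysed here. Of 14, 0 rose, 5 fell and 9 did not pass, and 0 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.00371; adjusted p = 0.123 with an estimated correlation). The list mean was -0.08, with -0.17 without normalization between arrays and -0.20 as deposited. The fallen genes were the cytoskeletal linkers TNS1 (-0.23 ± 0.04), TLN2 (-0.20 ± 0.03), TLN1 (-0.15 ± 0.03), ZYX (-0.12 ± 0.03) and the kinase SRC (-0.15), the last chosen after its values were seen.

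Genes of matrix turnover moved both ways, with 5 of 27 higher, 6 lower and 16 not passing, and 6 and 9 adjusted over the list alone (camera adjusted p = 0.175). The membrane collagenase MMP14 fell by 0.55 ± 0.04 on the log2 scale and the metalloproteinase inhibitor TIMP1 by 0.45 ± 0.04. ADAM19 fell by 0.39 ± 0.03 and CTSL by 0.36 ± 0.04 on that scale. Of 29 extracellular matrix genes 8 rose, 4 fell and 17 did not pass (9 and 4 adjusted over the list alone; camera adjusted p = 0.124). Fibronectin, FN1, rose by 0.53 ± 0.05, CCN2 by 0.59 ± 0.06 and HSPG2 by 0.28 ± 0.03. TGF-beta targets had 4 of 19 higher, 3 lower and 12 not passing (5 and 4 adjusted over the list alone; camera adjusted p = 0.190), and among them JUNB rose by 0.64 ± 0.05 and LTBP1 fell by 0.44 ± 0.05 on the log2 scale. Within numbers 1 to 3 and 4 to 6, the TGF-beta mean was 0.0346 (adjusted p = 0.743) and 0.120 (adjusted p = 0.0134), and the matrix gene mean 0.0511 (adjusted p = 0.159) and 0.0992 (adjusted p = 0.0290). As deposited both means were negative, -0.0328 and -0.0297, while camera called both lists higher relative to other genes (adjusted p = 0.0243 and 0.00864). All these calls used the preset correlation, and over the 12 arrays the TGF-beta list had adjusted p = 0.633 and the matrix list adjusted p = 0.276 with an estimated correlation.

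Of 32 hypoxia-responsive genes, 8 rose, 2 fell and 22 did not pass, with the same counts adjusted over the list alone, and the list was not called (camera adjusted p = 0.175). STC2 rose by 0.49 ± 0.04, DDIT4 by 0.43 ± 0.09, the vasodilator peptide gene ADM by 0.41 ± 0.05 and NDRG1 by 0.14 ± 0.03. ERO1A (-0.17 ± 0.03) and KDM4C (-0.14 ± 0.03) fell. Glycolysis enzymes had 1 of 10 higher, HK2 (0.17 ± 0.04), and 9 not passing, also when adjusted over the list alone (adjusted p = 0.813; the list's median was -0.01 and its mean 0.00474). GAPDH (0.07 ± 0.03, adjusted p = 0.126) and GPI (-0.07 ± 0.03, adjusted p = 0.184) did not pass.

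Of 55 mitosis genes, 1 was higher, 2 were lower and 52 did not pass (1, 0 and 54 adjusted over the list alone), and the list was not called (camera adjusted p = 0.175). CDC25B rose by 0.15 ± 0.03, and BUB3 (-0.12 ± 0.03) and SGO2 (-0.13 ± 0.04) fell, the latter called in 17 of 28 alternatives. SMC4 (-0.15 ± 0.06), HMMR (-0.21 ± 0.09) and KIF14 (-0.23 ± 0.09) did not pass. The list mean varied more between siCtrl arrays (SD 0.172, n = 6) than between siHuR arrays (SD 0.0138, n = 6). The mean was 0.285 higher on siCtrl arrays 1 to 3 than on 4 to 6. The siHuR minus siCtrl difference of the list mean was -0.17 within numbers 1 to 3 and 0.11 within numbers 4 to 6. DNA replication genes had 1 of 36 higher, 2 lower and 33 not passing, also when adjusted over the list alone (camera adjusted p = 0.414). The replicative helicase subunit MCM3 fell by 0.26 ± 0.03 on the log2 scale, MCM7 rose by 0.11 ± 0.03 and GINS4 fell by 0.12 ± 0.04 on the log2 scale, though its other probe set gave 0.00870 (adjusted p = 0.962 over all probe sets). The rise of MCM7 was as low as 0.00208 over the alternatives, and MCM7 was called in 22 of 28 of them. WDR76 (-0.10 ± 0.03), MCM2 (0.11 ± 0.05) and TYMS (0.11 ± 0.05) did not pass.

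**Figure D4:**
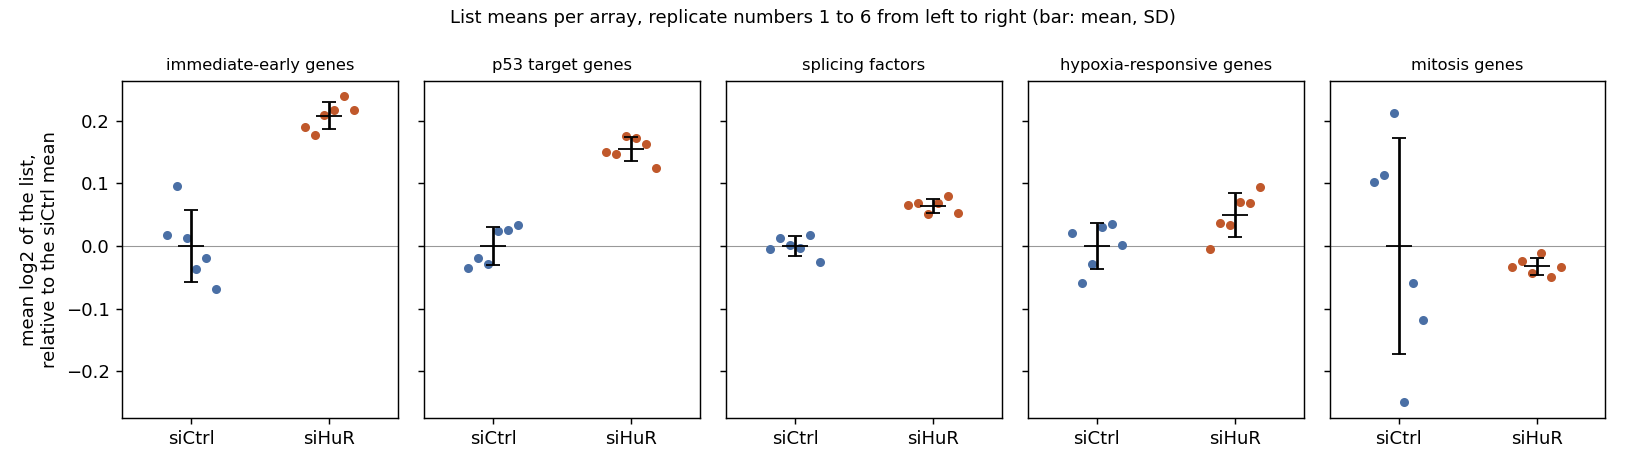
Mean log2 value of 5 gene lists on each array relative to the siCtrl mean (y axis), 6 arrays a group with mean and SD as bars. The immediate-early mean was 0.21 higher in siHuR, the splicing factor mean 0.06 higher (-0.0312 without normalization between arrays), and mitosis means ranged from -0.250 to 0.212 in siCtrl.

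Apoptosis regulators moved both ways (5 of 23 higher, 3 lower, 15 not passing, and 6 and 4 adjusted over the list alone; adjusted p = 0.389). The pro-apoptotic genes BCL2L11 (0.54 ± 0.06) and BAX (0.23 ± 0.04) rose, and the anti-apoptotic genes BCL2A1 (-0.48 ± 0.04) and BIRC2 (-0.19 ± 0.03) fell. NF-kB inflammatory genes had 6 of 31 higher and 1 lower, with 24 not passing (7 and 1 adjusted over the list alone; adjusted p = 0.192; median -0.00452, mean 0.09). As deposited the NF-kB mean was -0.00911, while camera called the list higher relative to other genes (adjusted p = 0.0173), but on the main scale the list had adjusted p = 0.384 with an estimated correlation. The NF-kB mean includes CCL2, whose 4.86-fold rise was the largest of all named genes, and the mean without CCL2 was not computed. IER3 rose by 0.32 ± 0.03 and LIF by 0.19 ± 0.05, and IL11 fell by 0.34 ± 0.06 on the log2 scale. Unfolded protein response genes had 4 of 22 higher and 3 lower, with 15 not passing (4 and 5 adjusted over the list alone; adjusted p = 0.813). Their median was -0.01, their mean 0.01 and the direction of the test lower. DDIT3 rose by 0.34 ± 0.05 and WFS1 by 0.25 ± 0.04. ATF4 amino acid response genes had 5 of 25 higher and 5 lower, with 15 not passing (7 and 8 adjusted over the list alone; adjusted p = 0.682), including CARS1, which fell by 0.26 ± 0.04 on the log2 scale.

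Autophagy and lysosome genes had 7 of 32 higher and 5 lower, with 20 not passing (8 and 6 adjusted over the list alone; adjusted p = 0.492), among them ATG14 (0.27 ± 0.04), CTSA (0.23 ± 0.03) and HEXA (0.23 ± 0.03), which rose. Double-strand break repair genes had 1 of 25 higher and 2 lower, with 22 not passing, and 0 were higher, 0 lower and 25 not passing adjusted over the list alone (adjusted p = 0.761). DCLRE1C (-0.12 ± 0.04) and BARD1 (-0.11 ± 0.04) fell, and PALB2 (0.10 ± 0.03) rose, but was -0.00153 without normalization between arrays. BARD1 and PALB2 were each called in 13 of 28 alternatives. Oxidative phosphorylation genes had 0 of 15 higher and 2 lower, CYC1 (-0.13 ± 0.03) and COX8A (-0.12 ± 0.03), also when adjusted over the list alone (adjusted p = 0.175). Their mean was 0.01 within numbers 1 to 3 (adjusted p = 0.840) and -0.0663 within numbers 4 to 6 (adjusted p = 0.0142), but over the 12 arrays the list had adjusted p = 0.569 with an estimated correlation. Small Cajal body RNAs, the tested members of a list written for small nucleolar RNAs, had 2 of 21 higher and 1 lower, also when adjusted over the list alone (adjusted p = 0.161). Other small nucleolar RNAs were not analysed here, and the list was called without siCtrl 5 (adjusted p = 0.0447) and within numbers 1 to 3 (adjusted p = 0.0370), but over the 12 arrays it had adjusted p = 0.534 with an estimated correlation. SCARNA17 rose by 0.28 ± 0.04 and SCARNA22 fell by 0.19 ± 0.05 on the log2 scale.

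Meningioma and arachnoid markers had 4 of 20 higher and 1 lower, with 15 not passing (5 and 2 adjusted over the list alone; adjusted p = 0.175). The transcription factor KLF4 rose by 0.44 ± 0.04, the tumour suppressor NF2 by 0.37 ± 0.04 and MN1 by 0.31 ± 0.03, and FOXD1 fell by 0.34 ± 0.05 on the log2 scale. The other FOXD1 probe set gave -0.215 and did not pass (adjusted p = 0.346 over all probe sets). Endothelial markers had 0 of 14 higher and 3 lower, with 11 not passing (0 and 4 adjusted over the list alone; adjusted p = 0.0506). TIE1 fell by 0.60 ± 0.03 on the log2 scale, ENG by 0.24 ± 0.04 and ECSCR by 0.25 ± 0.05. The other ECSCR probe set gave -0.111 and did not pass (adjusted p = 0.0985 over all probe sets). The endothelial list was called lower without any 1 of siCtrl 4, siHuR 3, siHuR 4 and siHuR 6 (adjusted p from 0.0302 to 0.0419) and as deposited (adjusted p = 0.0173), but over the 12 arrays it had adjusted p = 0.123 with an estimated correlation. Leukocyte markers had 0 of 13 higher and 2 lower, LAPTM5 (-0.48 ± 0.03) and CD68 (-0.17 ± 0.03), also when adjusted over the list alone (adjusted p = 0.521). Neuron and glia markers had 0 of 11 higher and 1 lower, OLIG2 (-0.12 ± 0.03), also when adjusted over the list alone (adjusted p = 0.682).

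Altogether 9 of 28 lists were called, 8 higher and 1 lower, and 3 of them held with an estimated correlation. Among the 28794 probe sets not named here, 1805 changed, 889 higher and 916 lower, and 62 changed at least 1.5-fold, 16 higher and 46 lower. Probe set 17093861 fell by 2.68 ± 0.10 on the log2 scale (6.40-fold lower), and the change of probe set 17033604 was -1.83 ± 0.05, while 16677556 rose by 1.40 ± 0.07 and 16660059 by 1.32 ± 0.04.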

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

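The tests of the siHuR mitosis gap, of the immediate-early rise within replicate numbers 1 to 3 with re-centred arrays and relative to each array's median, and the count of splits for lists with an estimated correlation were chosen after the results were seen. Of 100 splits of the 12 arrays into 6 and 6, drawn from 462, 1 gave as many changed genes, the real one (2223, highest other 0). The same held for 47 genes changed at least 1.5-fold (1 of 100, highest other 0). Splits that mix the groups carry the difference between them in the residuals, which lowers both counts. Low counts in the other splits were thus largely set in advance, and no conclusion on chance is drawn from them. Nor can the splits tell an siRNA effect from another difference between the cultures of the groups. For 9 called lists 5 of 100 splits gave as many and the highest other was 11, so chance cannot be excluded. With an estimated correlation 3 lists were called, 1 of 100 splits gave as many, the real one, and the highest other was 1. This count was added after the planned count of called lists had been seen. In splits that mix the groups, the difference between them enters the residuals and can raise the estimated correlation. Chance is therefore not excluded by this count.

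Mitosis genes separated the siCtrl arrays numbered 1 to 3 from those numbered 4 to 6, and 54 of 55 genes were higher in 1 to 3. The scaling of the arrays is argued against as the cause, since the siCtrl SD was 0.177 with re-centred arrays and 0.172 in the main setting. A batch shared by equal numbers in both groups is argued against by the siHuR gap of -0.00232, against 0.285 in siCtrl. A difference between the siCtrl cultures, such as their growth state, or a batch within siCtrl alone may remain, and the labels give neither.

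The immediate-early rise was 0.150 ± 0.028 within numbers 1 to 3, which argues against the state of siCtrl arrays 4 to 6 as its whole cause. With re-centred arrays it was 0.186 ± 0.041, which argues against quantile normalization as the cause. With log2 of the values as deposited it was 0.114 ± 0.074, which alone did not decide on the scaling of the arrays, but relative to each array's median of all named genes it was 0.233 ± 0.034, higher on 6 of 6 siHuR arrays than on any siCtrl array, which argues against a scale factor per array as the cause. The siRNA against ELAVL1, through HuR or through other transcripts, may be a cause, and with 1 siRNA these cannot be separated.

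The rise of reported HuR target mRNAs may rest on members shared with the immediate-early list (FOS, JUN, DUSP1, MYC and ATF3; 0 were shared with the p53 list). Without those 5, 6 of 31 genes rose and 1 fell, and the camera p was 0.0692 (p = 0.148 with an estimated correlation). The mean of these 31 genes was 0.0693, but -0.0245 without normalization between arrays and -0.0417 as deposited.

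Single arrays stood far from the other 5 of their group in 19 of 312 groups of 6 values, where chance gives 15.6, with 5 in siCtrl and 14 in siHuR. The value given is the gap to the nearest array over the whole range of the 6, and each exceeded Dixon's 95% critical value. High arrays were siCtrl 5 for C3 (0.653), siHuR 4 for PLXNA1 (0.704), siHuR 6 for DDIT4 (0.678), siCtrl 1 for MCM3 (0.684), siHuR 2 for CARS1 (0.810), siCtrl 6 for FAU (0.682), siHuR 5 for KLF4 (0.768) and siHuR 3 for KDR (0.646). Low arrays were siHuR 1 for PLXNA4 (0.655) and BIRC2 (0.663), siHuR 2 for MMP14 (0.733), siHuR 3 for COX8A (0.736) and SNRNP70 (0.766), and number 1 of both groups for RPL32 (0.737 in siCtrl and 0.660 in siHuR). Among list means, siHuR 4 was high for glycolysis enzymes (0.628), siCtrl 3 high for double-strand break repair (0.677), siHuR 6 low for cholesterol synthesis (0.711) and siHuR 2 high for oxidative phosphorylation (0.654).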

How the results depend on the processing

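The settings that used offset 16, the deposited scale, replicate numbers 1 to 3 or 4 to 6, the first probe set and the permutation of list means were chosen after seeing the data. Changed genes numbered 2223, but 1146 without normalization between arrays, 1442 as deposited, 3732 over all probe sets, 1131 with numbers 1 to 3 only and 1222 with numbers 4 to 6 only, the latter pair with fewer arrays. Leaving out 1 array gave 1951 to 2092. Genes changed at least 1.5-fold numbered 47, but 75 with offset 16, 74 as deposited, 117 tested for a change beyond 1.2-fold and 5 at 2-fold. Called lists numbered 9, but 3 with an estimated correlation, 15 with fry and 16 by exact permutation of list means, which do not compare a list with other genes. The HuR target list, with a mean of 0.151, lost its call with an estimated correlation (adjusted p = 0.123). The hypoxia list was -0.0533 as deposited, while camera called it higher relative to other genes (adjusted p = 0.0427), but on the main scale the list had adjusted p = 0.633 with an estimated correlation. The mitosis list was -0.0584 and called with re-centred arrays. camera called it lower with numbers 1 to 3 only (-0.175, adjusted p = 1.93e-21) and higher with numbers 4 to 6 only (0.112, adjusted p = 1.39e-07), all at the preset correlation. Over the 12 arrays its estimated correlation was 0.691 and its adjusted p = 0.828 with an estimated correlation. Leaving out 1 array it lay between -0.0825 (without siCtrl 4, called) and 0.00983 (without siCtrl 3), and at -0.0561 without siCtrl 6 it was called. PALB2 (-0.00153) and RPL24 (-0.00177) turned negative without normalization between arrays, PALB2 (-0.00694), RPL24 (-0.00427) and PUM2 (-0.00151) as deposited, and TIAL1 (-0.00401) with its first probe set. For TIAL1 the turn came with the change of probe set. The median of all genes moved by -0.0733 without normalization between arrays and by -0.104 as deposited. For PALB2, RPL24 and PUM2 the cause was not tested further. Arrays of equal number had residual correlations from -0.0581 to 0.0252, 0 over 0.1 and 0 best with their own number, and the replicate block gave 1972 changed genes, 1915 shared. Of 3547 values of named genes over the alternatives, 2807 were called in the same direction in both settings, 206 lost the call and 30 gained it with the same sign, and the 6 above lost it with the other sign. Of those called in neither setting, 485 had the same sign and 13 the other. The planned lists without ELAVL1 were not run.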

Other observations

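The tests of the ERK, YAP, plexin and complement lists were chosen after the results were seen. Each list was tested with all its members and again without the genes that had drawn attention to it, and only the latter test can tell against the hypothesis.

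CCN2, and ANKRD1, chosen after its values were seen, rose, and a rise across targets of the transcriptional coactivator YAP may be involved. Without them 7 of 10 target genes rose and 0 fell, with a mean of 0.19, or 0.0956 without normalization between arrays and 0.0989 as deposited (camera p = 6.20e-07; p = 0.0107 with an estimated correlation). This remains a hypothesis, since the list was written after the data were examined.

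SPRY4, DUSP4 and ETV4, which are induced by ERK signalling, fell, and a fall across ERK output genes might have accounted for this. Without those 3 genes, 1 of 6 rose, SPRY2 (0.16), and 1 fell, ETV5 (-0.20), both chosen after their values were seen. The camera p was 4.64e-05 with all members but 0.622 without SPRY4, DUSP4 and ETV4. No fall across the remaining genes was measured, but a test of 6 genes that moved both ways has little power. NRP1, PLXNA1 and PLXNA4 fell, but without them 1 of 8 plexin and neuropilin genes rose and 2 fell. The camera p was 0.806 without them and 0.00176 with all 11 members (p = 0.0843 with an estimated correlation). C3, C4A and C4B rose, but without them 1 of 5 complement genes rose and 0 fell. The camera p was 0.602 without them and 2.16e-05 with all members.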
